A study of Arabidopsis thaliana with 9 samples.

How the data were processed

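RNA, nucleosome DNA and naked DNA came from rosette leaves of Arabidopsis plants treated with water or 5 µM coronatine for 1 h. Per the labels, harvested tissue was ground and divided into aliquots for these preparations. The 9 samples fall into 5 groups: RNA with water (2 libraries), RNA with coronatine (2), nucleosome DNA with water (2), nucleosome DNA with coronatine (2) and naked DNA with water (1). Libraries gave single-end reads for RNA and paired-end reads for DNA, of 50 bp, per the labels' protocols. No label says that replicates came from separate plants or pools, so p-values measure only the spread between these libraries, which may be technical.

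For RNA, the deposited table holds FPKM per gene and library, made with TopHat and Cufflinks on TAIR10, per the submitters' processing notes. The header names no unit; FPKM is taken from those tools and from the values. Versions, annotation, strand handling and the treatment of reads with several positions are not given in the sources used here. For nucleosomes, the deposited table holds a coverage signal per base, made with Bowtie on TAIR10, per the submitters' processing notes. All values below 4 were whole multiples of 1 step per column (0.0232 for control, 0.0244 for COR, tolerance 0.0011), as from whole fragments with 1 scaling factor. It has 1 column per condition where the labels list 2 libraries, so each was used as the authors' pooled value without SD or n. That these columns pool both libraries is an assumption, kept wherever they are called pooled below. In addition, 1 column of per-sample values was not used in any step, because its name fits the label of no sample; naked DNA was therefore not analysed here.

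Fitted values come from limma 3.58.1 in R 4.3.3, on log2(FPKM + 1) with the trend and robust options. Genes needed a mean of at least 1 FPKM over all 4 libraries. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes. An FPKM of exactly 0 can be a failed estimate, so such genes are given per library. FPKM tables carry no total read count; relative depth came from the step of low values in 872 genes. On simulated data with 18223 genes and 200 changed, the fit recovered 68% of 2-fold and 91% of 4-fold changes, and 4.79% of its 167 calls were false.

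Gene names came from an annotation of assembly TAIR10.1, which held 33394 of the 34133 table rows. Its nuclear chromosomes were set against the occupancy table: toward both ends of each of the 5 chromosomes, mean occupancy was lowest 14 to 33 bp outside the annotated gene ends. No coordinates from it are given. It carries no strand, so the planned window upstream of the gene start was replaced by windows at both ends of a gene: 200 bp outside, 200 bp inside, and the body between. Results that need the genome sequence (GC content, runs of A or T, G-boxes) were not run.

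Occupancy was divided by the mean over chromosomes 1 to 5, and changes are log2 ratios with a pseudocount of 0.1 in windows of at least 0.1. Other log2 ratios and log2 levels of occupancy carry the same pseudocount, so a log2 level of 0 lies below the nuclear mean. The planned tests of occupancy between libraries could not be made on pooled columns. In their place, the median change of a gene list was set against 10000 random lists of the same size, matched on mRNA level (mean of the 4 libraries) in 50 bins, or in fewer bins when other traits were matched as well. In simulated changes of 597 such genes, a planted shift of 0.02 gave percentile 99.3, and no shift gave percentile 70.1. Medians replaced the planned means; for genes higher with COR, the mean change inside gene ends was 0.047 against 0.0079 in other genes. Spacing was the first peak of the autocorrelation between 120 and 250 bp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.

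Before the data were examined, 21 gene lists with 201 members, the comparisons, the alternatives and the rule for named genes were fixed. The rule took the 10 largest rises and the 6 largest falls past the threshold with no overlap between conditions, up to 4 members per list with the smallest p, and MYC2, COI1, LOX2, VSP2 and JAZ10. In addition, 5 members were dropped because the annotation did not pair their locus with the symbol. They were JOX1 to JOX4 and IGPS; the loci AT5G05600 and AT2G38240, listed as JOX2 and JOX4, appear by locus. Set tests were camera with a preset correlation of 0.01, camera with an estimated correlation and fry, in 18 lists with at least 3 tested members. Alternatives were another pseudocount, no low-value filter, quantile normalization, limma without trend and robust options, a replicate block, leaving out each library, other windows and isolated genes.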

Results

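The series measured mRNA and nucleosome occupancy in rosette leaves of 4-week-old Arabidopsis thaliana plants of the Columbia-0 accession, 1 h after treatment with 5 µM coronatine (COR) or with water. Coronatine is a bacterial toxin that mimics jasmonoyl-isoleucine, the active form of the stress hormone jasmonate. It binds the receptor COI1 and leads to degradation of the JAZ repressors. The design text asks how mRNA abundance and nucleosome occupancy respond to coronatine. RNA sequencing had 2 libraries per condition. Nucleosome DNA, the DNA left after digestion of nuclei with micrococcal nuclease (MNase), also had 2 libraries per condition in the labels, but its deposited table holds 1 column per condition.

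The RNA table held 34133 genes per library, of which 18223 had a mean of at least 1 FPKM over the 4 libraries and were tested. Summed FPKM values lay between 829063 and 844664 per library. The size of 1 read in low genes gave depths, relative to control replicate 1, of 0.877 for control replicate 2, 0.901 for COR replicate 1 and 1.14 for COR replicate 2. Log2 values correlated across genes at r = 0.987 between the control libraries and r = 0.984 between the COR libraries, against 0.970 to 0.973 between conditions. The occupancy columns were whole multiples of 1 step each, and corresponded to a mean of 55.0 fragments per nuclear base in control and 52.6 with COR.

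The first comparison asks which mRNAs changed after 1 h of coronatine. Genes of the jasmonate pathway were among the largest rises: most JAZ repressors, most genes for enzymes that make or break down jasmonate, and the transcription factor gene MYC2. Also higher were 12 of 17 genes of glucosinolate synthesis, 6 of 6 of tryptophan synthesis and 6 of 9 ethylene response factors. With an estimated correlation, camera gave an adjusted p = 0.243 for each of these 3 lists, while fry gave an adjusted p = 0.0255 for each. For the 5 jasmonate lists the camera adjusted p then lay between 0.090 and 0.317, so none passed on that setting. Their fry adjusted p lay between 0.00106 and 0.0255. The camera setting raised p even for the JAZ and turnover lists, whose estimated correlations (-0.031 and -0.079) lay below the preset. Failing it therefore does not decide whether a list changed. Genes of photosynthesis, abscisic acid and cold response, and the circadian clock had no member past the threshold in either direction. In total, 643 genes were higher and 494 were lower with COR (limma, Benjamini-Hochberg adjusted p under 0.05), of which 261 were higher and 19 lower by at least 2-fold.

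The split of the calls depended on the settings. The share of higher genes among the calls was 56.6% as deposited and 66.7% after quantile normalization (682 higher, 341 lower). The lower count fell to 210 with no low-value filter, to 217 without limma's trend and robust options and to 184 with a replicate block. It was 98 without control replicate 1, 117 without control replicate 2 and 281 without COR replicate 2, and the higher count was 418 and 426 without either control library. The 19 genes lower by at least 2-fold became 35 with a pseudocount of 0.1, 32 to 44 when 1 library was left out and 11 without genes listed at 0 in any library.

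JAZ proteins repress jasmonate-responsive transcription, and 10 of the 11 JAZ genes tested rose, also 10 when adjusted over the list alone. JAZ8 rose from 1.103 ± 0.0376 to 39.6 ± 2.37 FPKM (SD, n = 2), a log2 fold change of 4.27 with a standard error of 0.0775 on the log2(FPKM + 1) scale (limma adjusted p = 4.77e-06). JAZ9, the JAZ gene with the highest level under COR, rose from 107 ± 1.49 to 1172 ± 30.0 FPKM. JAZ7 rose from 2.19 ± 0.515 to 62.3 ± 9.72 FPKM, JAZ10 from 4.24 ± 0.402 to 58.5 ± 7.19 FPKM, and JAZ6 and JAZ2 by log2 fold changes of 2.32 and 2.89. JAZ11, named after its values were seen, was the 1 member that did not pass, with 10.5 FPKM in control and 11.4 with COR. JAZ4 lay below 1 FPKM and was not tested. The list median was 2.89. The set test camera gave an adjusted p = 7.53e-29 at its preset correlation and an adjusted p = 0.090 with an estimated correlation. That estimate was -0.031, below the preset of 0.01, so correlation among the JAZ genes does not account for the higher p. The rotation test fry, which asks whether the members move one way on balance, gave an adjusted p = 0.00106.

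**Figure D1:**
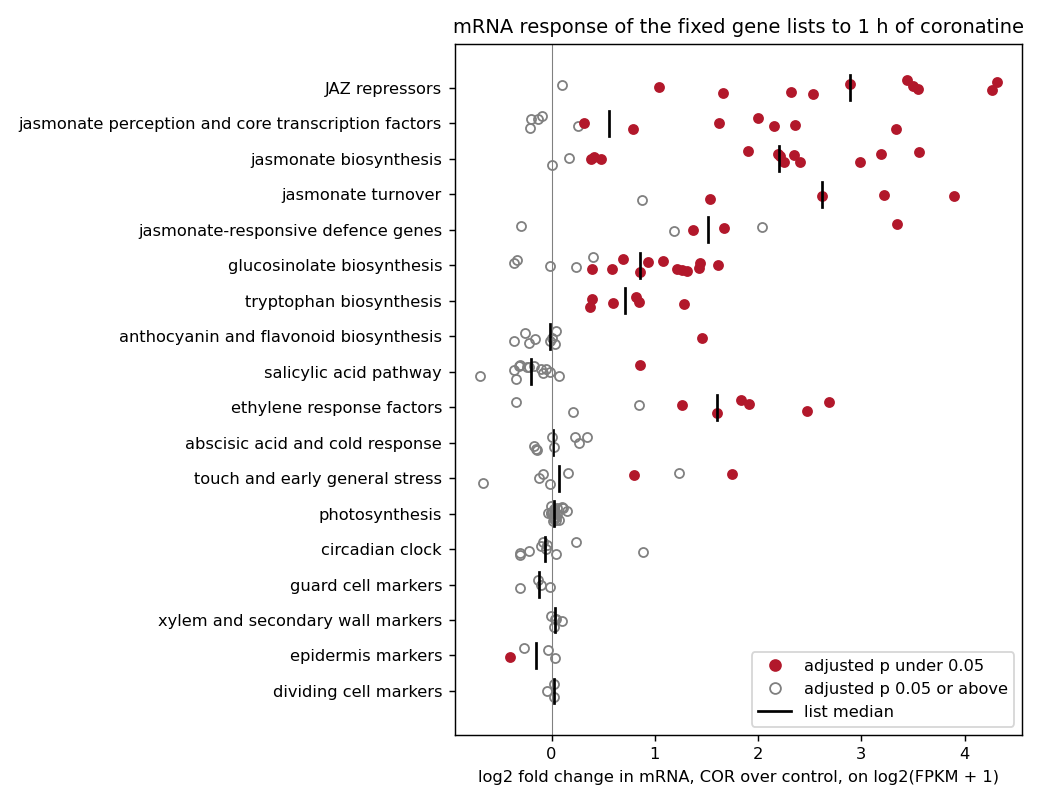
Each point is 1 gene, placed by its log2 fold change in mRNA on the log2(FPKM + 1) scale (x axis) in the fixed list it belongs to (y axis, lists with at least 3 tested members). Filled points passed an adjusted p of 0.05 in limma, open points did not, and bars mark list medians; the JAZ median lies at 2.89 and the photosynthesis median at 0.027.

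Among jasmonate perception genes and core transcription factors, 7 of 12 rose (8 higher and 2 lower when adjusted over the list alone). MYC2, the main transcription factor of the jasmonate response, rose from 14.1 ± 0.214 to 152 ± 20.3 FPKM (log2 fold change 3.33, limma adjusted p = 3.4e-05). ANAC055, a NAC factor downstream of MYC2, rose by 2.00 on the log2 scale, and the MYC-related repressors JAM1 and JAM2 rose by 1.62 and 0.79. The receptor gene COI1 had 16.6 ± 0.387 FPKM in control and 14.2 ± 1.36 FPKM with COR (limma adjusted p = 0.222). The camera adjusted p = 2.83e-08 at the preset correlation became an adjusted p = 0.317 with an estimated correlation.

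Jasmonate biosynthesis had 12 of 14 tested members higher, and 13 when adjusted over the list alone. OPR3, which reduces the jasmonate precursor OPDA in the peroxisome, rose from 41.9 ± 2.28 to 503 ± 24.4 FPKM (log2 fold change 3.55, limma adjusted p = 4.77e-06). The chloroplast enzymes LOX2, AOS and LOX3 rose by 2.25, 1.91 and 2.99, LOX2 from 170 ± 1.78 to 814 ± 28.9 FPKM. For this list the camera adjusted p = 9.42e-28 became an adjusted p = 0.090 with an estimated correlation. Of the 5 tested genes of jasmonate turnover, 4 rose, and 5 when adjusted over the list alone. CYP94C1, which oxidises jasmonoyl-isoleucine, rose from 7.94 ± 0.764 to 132 ± 0.641 FPKM (limma adjusted p = 4.77e-06). The amidohydrolase genes ILL6 and IAR3 rose by 3.22 and 2.62, and the methyltransferase gene JMT by 1.54. The camera adjusted p = 5.81e-14 of the turnover list became an adjusted p = 0.095 with an estimated correlation, though that estimate, -0.079, also lay below the preset.

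Of 6 tested jasmonate-responsive defence genes, 3 rose, and 5 when adjusted over the list alone. CLH1, a chlorophyllase gene, rose from 33.1 ± 3.56 to 345 ± 14.7 FPKM (limma adjusted p = 1.74e-05). The aminotransferase-family genes TAT3 and CORI3 rose by 1.37 and 1.67. VSP2, a vegetative storage protein gene, had 2.89 ± 1.63 FPKM in control and 14.3 ± 0.170 FPKM with COR, and did not pass (limma adjusted p = 0.0679). The list's camera adjusted p = 4.56e-09 became an adjusted p = 0.128 with an estimated correlation.

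**Figure D2:**
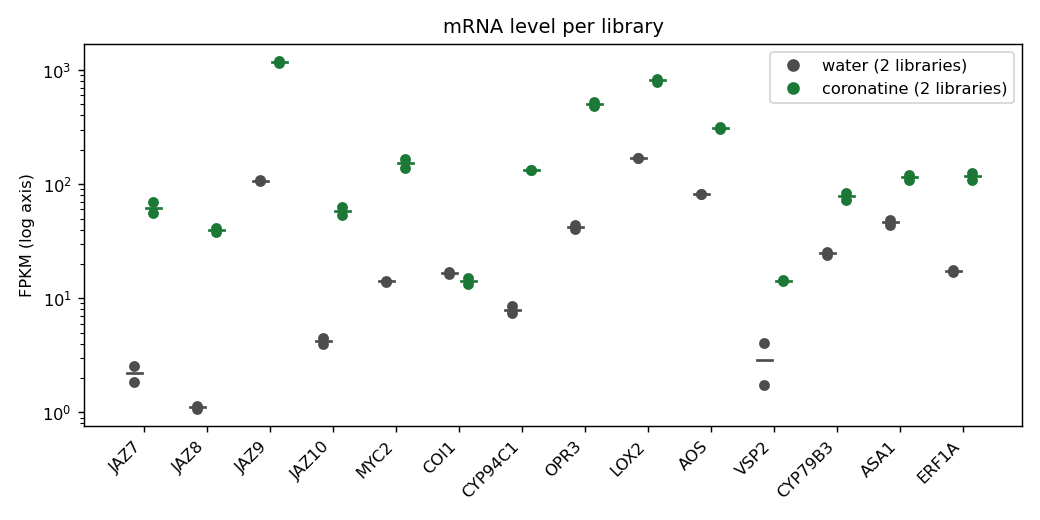
Points are single RNA libraries (2 with water, 2 with coronatine), bars their group means, in FPKM on a log axis, for 14 genes of the fixed lists. JAZ8 lay at 1.13 and 1.08 with water and at 37.9 and 41.3 with coronatine, while COI1 lay at 16.8 and 16.3 with water and at 13.3 and 15.2 with coronatine.

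Glucosinolates are sulphur-containing defence compounds of the cabbage family. Of their 17 tested biosynthesis genes, 12 rose, against 14 higher and 1 lower when adjusted over the list alone. The indole branch genes CYP79B3 and CYP79B2 rose by 1.61 and 1.43, CYP79B3 from 24.9 ± 1.12 to 78.4 ± 8.16 FPKM (limma adjusted p = 2.74e-04). The glucosyltransferase gene UGT74B1 rose by 1.31 and MYB34, a regulator of the indole branch, by 1.44. All 6 tryptophan biosynthesis genes rose, also 6 when adjusted over the list alone, although 3 passed without control replicate 2. ASA1, the subunit of anthranilate synthase that starts the pathway, rose from 46.5 ± 3.19 to 115 ± 8.12 FPKM (limma adjusted p = 4.35e-04). ASB1, TSB2 and TSB1 rose by 0.85, 0.82 and 0.59; the near-identical pair TSB1 and TSB2 can share reads. Camera gave an adjusted p = 5.85e-17 for glucosinolates and an adjusted p = 8.2e-12 for tryptophan, and an adjusted p = 0.243 for both with an estimated correlation.

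Ethylene response factors rose in 6 of 9 cases, against 7 higher and 1 lower when adjusted over the list alone. ERF1A rose from 17.3 ± 0.379 to 117 ± 11.3 FPKM and ERF2 from 38.1 ± 0.525 to 217 ± 38.8 FPKM (limma adjusted p = 2.54e-05 and 7.34e-04). ORA59, which acts in joint jasmonate and ethylene responses, rose by 1.92, and RAP2.6 by 1.61. The camera adjusted p = 7.84e-11 became an adjusted p = 0.243 with an estimated correlation. Of 8 touch and early stress genes, 2 rose, also 2 when adjusted over the list alone: WRKY18 from 81.1 ± 2.58 to 275 ± 24.3 FPKM and WRKY40 from 22.6 ± 0.227 to 40.4 ± 6.10 FPKM. WRKY40 did not pass without control replicate 1 or without control replicate 2. ZAT10 and WRKY53 did not pass (log2 fold changes 1.23 and -0.67). The camera adjusted p = 0.0153 became an adjusted p = 0.253 with an estimated correlation, and fry gave an adjusted p = 0.0614.

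In the salicylic acid list, 1 of 14 genes rose, also 1 when adjusted over the list alone. This was EDS5, the transporter gene of the salicylate pathway, at 14.2 ± 0.910 FPKM in control and 26.6 ± 2.02 FPKM with COR (limma adjusted p = 0.00246). EDS1, PAD4 and NIMIN1 had log2 fold changes of -0.35, -0.37 and -0.69 and did not pass; 3 members passed as lower without COR replicate 2. Of 9 anthocyanin and flavonoid genes, 1 rose (1 higher and 1 lower when adjusted over the list alone): PAP1, a MYB activator of anthocyanin synthesis, from 1.71 ± 0.376 to 6.49 ± 1.47 FPKM. The enzyme genes CHS, UF3GT and LDOX did not pass, with log2 fold changes of -0.21, -0.36 and -0.25. That list's median was -0.014, its mean 0.060, camera pointed up and fry down, neither past the threshold (adjusted p = 0.653 and 0.791).

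No gene passed in the abscisic acid and cold list (8 tested) or in the circadian clock list (10 tested, with 1 higher and 1 lower when adjusted over the list alone). At an unadjusted p under 0.05, limma had 1174 genes higher and 2447 lower over all tested genes; the lower count was 1475 without control replicate 1 and 1578 without control replicate 2. KIN1, KIN2, COR15A and ABI1 had log2 fold changes of 0.34, 0.27, 0.23 and -0.17. The clock genes CCA1, PRR5, PRR9 and LUX had -0.31, 0.89, -0.30 and 0.23, CCA1 with an adjusted p = 0.050 in limma. None of 20 photosynthesis genes passed, over all genes or adjusted over the list alone. Their median was 0.027, while the median of all tested genes was -0.059. RBCS2B, RBCS3B, LHCA2 and LHCB4.1 had 0.15, 0.11, 0.10 and 0.069; RBCS genes are near-identical copies that can share reads. The camera adjusted p = 0.00382 of photosynthesis became an adjusted p = 0.651 with an estimated correlation, and fry gave an adjusted p = 0.679.

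Few markers of leaf cell types passed. None of 4 guard cell, 2 phloem, 5 xylem and 3 dividing cell markers passed, and 1 of 4 epidermis markers was lower. This was KCS10, a cuticle lipid gene, with 181 ± 4.65 FPKM in control and 137 ± 0.719 FPKM with COR (limma adjusted p = 0.00814), which did not pass without control replicate 1 or without control replicate 2. When adjusted over the list alone, 1 guard cell marker and 2 epidermis markers were lower. MYB60, SUC2, XCP1 and KNOLLE had log2 fold changes of -0.31, 0.040, 0.11 and 0.020. The 1 root marker tested, NRT2.1, had a log2 fold change of 0.68 and passed only when adjusted over the list alone. None of the 7 flower markers reached 1 FPKM.

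Other large rises were outside the tested lists. AT2G38240, dropped from the jasmonate turnover list as JOX4, rose from 0.855 ± 0.211 to 36.2 ± 11 FPKM. AT5G05600, dropped from that list as JOX2, rose from 13.7 ± 1.2 to 253 ± 14.4 FPKM. AT4G17470 and AT3G22275 rose by log2 fold changes of 3.90 and 3.86. The rule for the largest changes also took genes listed at exactly 0 in a condition, for which no fold is given. ECT2, a gene for a reader protein of methylated RNA, was listed at 0 in both control libraries and at 99.0 and 101.0 FPKM with COR. ATCG00320 and AT5G40981 were listed at 0 in control and at 36.1 and 43.3, and at 12.8 and 15.2 FPKM, with COR. All 6 falls that the rule took were listed at 0 in both COR libraries. They were ATCG00460 (40.8 and 46.9 FPKM in control), AT1G28730 (39.33 and 44.95), MIR156d (31.9 and 36.2), SNOR108 (20.6 and 23.7), AT2G29628 (4.16 and 9.46) and AT3G53611 (2.65 and 6.09). Without genes at 0 in any library, 669 genes were higher and 566 lower. Among genes above 0 in every library, named after their values were seen, AT5G41900 fell from 14.3 to 3.93 FPKM, AT2G41170 from 20.3 to 8.07 and AT5G62730 from 12.4 to 4.82 FPKM.

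Transcripts of the plastid genome were lower with COR. They made up 0.652% and 0.600% of the summed FPKM in the control libraries and 0.429% and 0.393% in the COR libraries. Of 78 plastid-encoded transcripts tested, 15 were lower and 1 was higher, with a median log2 fold change of -0.45. Of 13 mitochondrion-encoded transcripts, 4 were lower and none higher, with a median of -0.26. Without both groups, 649 genes were higher and 497 lower.

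The next comparison relates occupancy to mRNA level, the question of the series title. Among genes not listed at 0 in both control libraries, occupancy was lower at genes with more mRNA. It is given relative to the nuclear mean, for 24126 protein-coding genes of at least 800 bp. In control, the 200 bp just inside both gene ends had a mean of 1.15 ± 0.362 (SD across genes) in the lowest quintile of expressed genes and 0.829 ± 0.283 in the highest. The gene body beyond had 1.07 ± 0.325 and 0.879 ± 0.222, and the 200 bp outside the ends 1.09 ± 0.357 and 0.827 ± 0.305. Genes listed at 0 in both control libraries had 1.12 inside, 1.13 outside and 1.025 in the body. Inside and in the body they lay below the lowest quintile. With COR, the inside means were 1.15 and 0.840 in the lowest and highest quintile.

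The average profile had a minimum of 0.888 at 23 bp outside the gene end in control and 0.913 at 21 bp outside with COR. In the highest quintile the control minimum was 0.718, in the lowest 1.08. Across the 21156 genes not listed at 0 in both control libraries, Spearman's rho between control mRNA level and control occupancy was -0.27 outside, -0.33 inside and -0.30 in the body. With COR occupancy it was -0.26, -0.31 and -0.29. Genes are not independent replicates, so no p is given. The mean log2 ratio of outside over inside was -0.067 in control and -0.041 with COR, but 0.019 and 0.056 among 6251 genes with no neighbour within 500 bp.

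**Figure D3:**
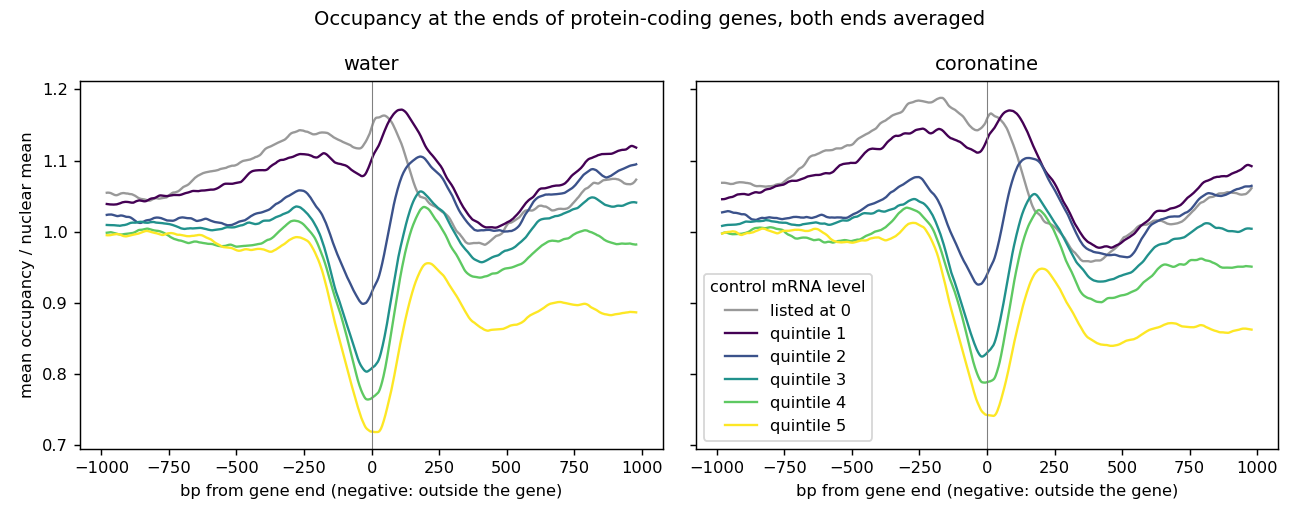
Mean occupancy relative to the nuclear mean (y axis) against distance in bp from the gene end (x axis, negative outside the gene, both ends averaged), for genes listed at 0 and for quintiles of control mRNA level. In control, the lowest point of quintile 5 lies at 0.718 and that of quintile 2 at 0.898; lines are running means over 21 bp without error bars.

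Photosynthesis genes, among the most expressed in the leaf, at 497 to 11360 FPKM in control, had a median log2 control occupancy of -0.52 outside the gene ends, -0.86 inside and -0.99 in the body. Random lists matched on mRNA level had medians of -0.29, -0.28 and -0.22 in these windows. The photosynthesis genes lay at percentile 4.03 outside, and below all random lists inside and in the body. Too few other genes reach such levels for the random lists to match photosynthesis genes closely. Whether this occupancy is low for their expression therefore stays open. LHCB4.1, a light-harvesting protein gene, had a body occupancy of 0.256 in control and 0.269 with COR, and LHCA2 had 0.514 and 0.526. Copies such as the RBCS genes can lose reads that map to several places, so their values are uncertain.

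The last comparison asks whether occupancy changed with coronatine where mRNA changed. With 1 pooled column per condition there is no replicate check and no test; percentiles among random lists describe these columns. Just inside their ends, the 597 genes higher with COR that had windows had a higher occupancy change than other genes, with a median log2 change of 0.050 against 0.011. That median lay at percentile 99.98 of 10000 random lists matched on mRNA level. The shift was small beside the SD of this change across tested genes, 0.219. Of the higher genes, 59.1% were above 0, against 52.1% of other genes. Outside the ends the median of the higher genes was 0.038 (percentile 74.1). In the body it was -0.021 against -0.047 in other genes, above all random lists. Their control body occupancy, at a median log2 of -0.047 with the pseudocount of 0.1, lay below all random lists matched on mRNA level. The median of those lists was 0.090.

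The 427 genes lower with COR had a median change of 0.066 outside the ends (percentile 99.79), 0.031 inside (percentile 91.5) and -0.014 in the body (above all random lists). Their control body occupancy, at 0.028 on the same log2 scale against a random median of 0.114, also lay below all random lists matched on mRNA level. Among genes with no neighbour within 500 bp, the excess of these lower genes over other genes was 0.0062 outside and -0.011 inside. There, the excess of the higher genes was 0.037 outside their ends, against 0.0080 in all genes, and 0.042 inside. Across 16999 tested genes, Spearman's rho between the change in mRNA and the change in occupancy was 0.0013 outside and -0.0034 inside. For the body it was -0.031 across 17000 genes.

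Together, the 47 genes of the 5 jasmonate lists with windows had a median change of 0.155 inside their ends (percentile 99.99), and 72.3% of them were above 0, against 52.3% of other genes. Outside the ends the median was 0.133 (percentile 99.3). Occupancy inside the ends went from 0.773 to 1.17 at JAZ5, from 0.943 to 1.45 at JAZ6 and from 0.862 to 1.33 at LOX2. At JAZ8 it went from 1.09 to 1.28, at JAZ7 from 0.811 to 0.971, at JAZ10 from 0.895 to 1.17 and at CYP94C1 from 0.963 to 1.21. OPR3 went from 0.617 to 0.656. Of the genes of these lists named here, those lower inside the ends with COR were MYC2 from 0.990 to 0.810, JAM2 from 0.989 to 0.772, JAZ2 from 0.833 to 0.736, CORI3 from 1.39 to 1.24 and TAT3 from 1.127 to 1.025. Of the large rises outside the tested lists, AT2G38240 went from 0.774 to 0.827 and AT4G17470 from 1.54 to 1.52. AT5G05600 went from 0.695 to 0.985 and AT3G22275 from 1.11 to 1.36. At COI1 the value outside the ends went from 0.730 to 1.35, and the value inside from 0.434 to 0.443.

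**Figure D4:**
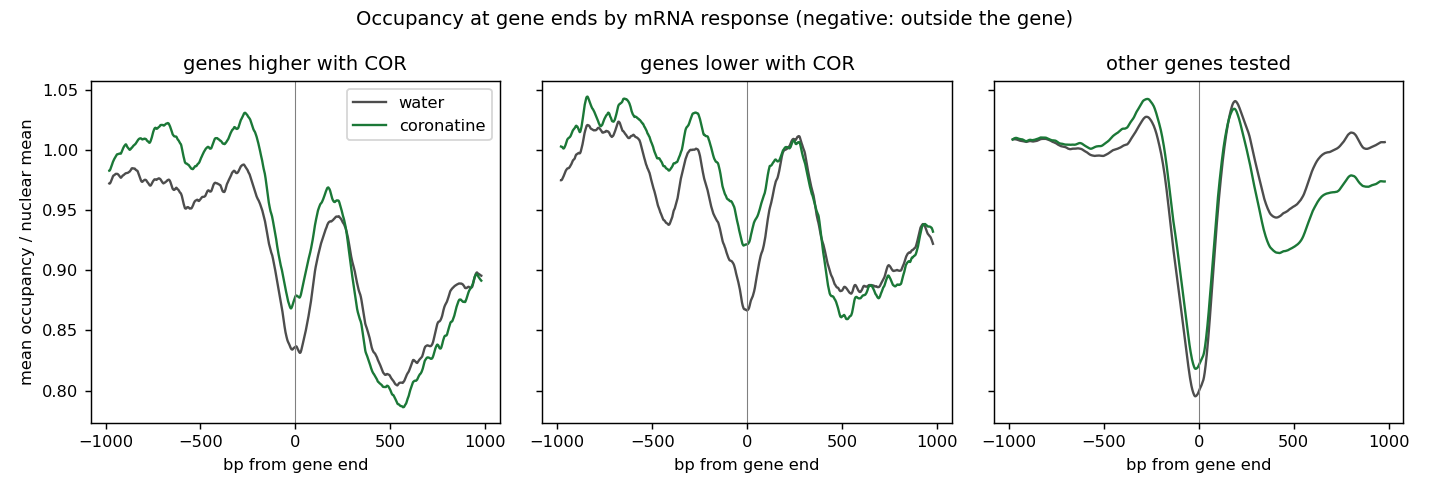
Mean occupancy relative to the nuclear mean (y axis) against distance in bp from the gene end (x axis, negative outside the gene) with water and with coronatine, for genes higher with COR, genes lower with COR and other tested genes. The lowest point near the gene end lay at 0.831, 24 bp inside, with water and at 0.868, 23 bp outside, with coronatine in the higher genes, at 0.867, 1 bp outside, and 0.921, 19 bp outside, in the lower genes, and at 0.795, 18 bp outside, and 0.818, 17 bp outside, in the others; each line is 1 pooled column, without error bars.

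Spacing of nucleosomes along genes could not be read with confidence. In genes of at least 1500 bp, the autocorrelation of control occupancy had a shallow peak at 174 bp (0.106, against 0.1051 at the minimum before it, at 164 bp). With COR no peak appeared in these genes, and in genes of at least 3000 bp there was a shoulder at 170 bp. After removal of a 500 bp moving average neither condition had a peak.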

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

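Plastid DNA in the nucleosome preparations differed between conditions, in data that no comparison above uses. Its mean coverage relative to the nuclear mean was 1.52 in control and 2.17 with COR, a ratio of 1.43. Over 104 bins of 1 kb the ratio lay between 1.27 and 1.63 (percentiles 5 to 95 of the bins). Mitochondrial DNA had 0.306 in control and 0.314 with COR, a ratio of 1.03. These means include bases listed at 0 in control, 33.6% of plastid and 70.8% of mitochondrial bases. Each condition has 1 pooled column, so the spread between preparations is unknown. Plastid transcripts went the other way in the RNA libraries, at 0.652% and 0.600% of the summed FPKM in control and 0.429% and 0.393% with COR.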

How the results depend on the processing

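Settings without plastid and mitochondrial genes, without genes listed at 0, with protein-coding nuclear genes above 0 in every library, and with a moving average removed were chosen after the data were seen. So were the strandless windows and the matching on length and control occupancy. Genes higher with COR, 643 as reported, numbered 418 to 537 when 1 library was left out; lower genes, 494 as reported, numbered 98 to 356. A fit without 1 library assumes that the lone library of that group varies like the other group. With no low-value filter 210 genes were lower and without limma's trend and robust options 217; the cause was not tested. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at 0.00183. With the replicate block, 497 genes were higher and 184 lower. Genes lower by at least 2-fold, 19 as reported, numbered 32 to 44 when 1 library was left out, 35 with a pseudocount of 0.1, 11 without genes listed at 0 and 9 among protein-coding nuclear genes above 0. At an unadjusted p, 1475 to 2646 genes were lower (2447 as reported) when 1 library was left out. JAZ genes past the threshold stayed within 1.5 times of 10 in each of the 12 alternatives.

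At genes higher with COR, the excess change outside gene ends moved from 0.0080 to 0.037 in isolated genes. The excess inside the ends moved from 0.039 to 0.027 with a pseudocount of 0.5. In the body it moved from 0.027 to 0.0194 with that pseudocount and 0.0195 in isolated genes. At genes lower with COR, isolated genes gave 0.0062 outside (0.036 as reported) and -0.0113 inside (0.019 as reported). The body excess of these genes, 0.034, was 0.0427 after quantile normalization and 0.0254 with a pseudocount of 0.5. The log2 ratio of outside over inside turned from -0.067 to 0.0194 in control and from -0.041 to 0.0558 with COR in isolated genes. The cause of these moves was not tested.

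No paired analysis or leaving out of replicates was possible for occupancy because its columns are pooled. Division by naked DNA, the GC content bins and the G-box flanks were not run. Spacing with a moving average removed gave no value. Of the named genes' alternatives, 16 lost a call, 15 gained one and 1105 did neither. No gene that passed in the reported fit or in the alternative turned its direction there. Turns among genes that passed in neither were not counted. FPKM without read counts limits what can be said of low genes.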

Other observations

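The gene family tests were run only after the main results were seen, as were the tests of plastid transcripts above 0, of ECT2's length, of induction and of the pooled libraries. Of 14 tested SAUR genes, which are early auxin-responsive genes linked to cell expansion, 6 were lower (Fisher's exact test, adjusted p = 3.23e-04 over 234 tests). The tests covered 117 families named by symbol. The comparison set was the 7303 tested genes with a numbered symbol, of which 2.90% were lower. SAUR29 fell from 22.1 ± 0.220 to 13.4 ± 1.41 FPKM (SD, n = 2) and SAUR24 from 4.67 ± 0.574 to 2.24 ± 0.0151 FPKM. Of 12 alpha-expansin genes, whose proteins loosen cell walls, 4 were lower (exact adjusted p = 0.0222), among them EXPA8 from 15.8 ± 1.87 to 8.63 ± 0.401 FPKM and EXPA1 from 192 ± 7.37 to 124 ± 11.6 FPKM. Of 14 KCS genes, which elongate very-long-chain fatty acids for wax, 4 were lower (exact adjusted p = 0.0257), with KCS12 falling from 59.5 ± 10.1 to 26.8 ± 0.633 FPKM. KCS10, also 1 of the 4, is an epidermis marker that did not pass without control replicate 1 or without control replicate 2 (log2 fold change -0.40). ATML1, another epidermis marker, had -0.27 and passed only when adjusted over the list alone; the other 2 markers, PDF1 and CUT1, had 0.035 and -0.038. SAUR genes are tandem copies, so reads of neighbours can be shared.

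Of 49 MYB genes, 8 were higher and 7 lower (exact adjusted p = 0.0432 and 0.0257). MYB47 rose from 1.82 ± 0.0257 to 16.7 ± 2.82 FPKM and MYB95 from 4.17 ± 0.0711 to 20.1 ± 2.37 FPKM. MYB4, MYB96, MYB111, MYB20, MYB94, MYB30 and MYB16 fell by 0.83, 0.62, 0.62, 0.61, 0.48, 0.38 and 0.35 on the log2 scale. Of 16 BBX genes, zinc finger factors of light signalling, 4 were lower and 1 higher (exact adjusted p = 0.0372 for lower), BBX14 falling from 152 ± 8.44 to 108 ± 8.26 FPKM. Of 20 ERF genes, 6 were higher and none lower (exact adjusted p = 0.0222 for higher), and 6 were higher after quantile normalization. ERF1A and ERF2 of the fixed list were among them. None of 156 EMB genes, required for embryo development, was higher or lower (exact adjusted p = 0.0432 and 0.467). After quantile normalization no called member of the SAUR, EXPA, KCS, MYB or BBX families turned its sign, but 4 SAUR, 4 EXPA, 4 KCS, 4 MYB and 3 BBX genes were lower, and 1 SAUR, 10 MYB and 1 BBX gene higher. Family members are not independent of one another, and the lower calls depend on the control libraries (98 without control replicate 1 and 117 without control replicate 2).

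In the RNA table, 6 genes were listed at 0 in both control libraries and at 5 FPKM or more in both COR libraries, and 5 the other way round. Pairs made of 1 control and 1 COR library held a mean of 3.5 such genes, against 5.5 in the real pairs, a ratio of 0.636, so such zeros also arise without regard to treatment. Genes at 0 in 1 library and at 5 FPKM or more in another were under 400 bp in 85.6% of cases, against 0.824% elsewhere, a ratio of 103.9. Failed estimates of short genes may therefore account for most of the pattern, but ECT2 has a length of 4030 bp, which argues against that for this gene. An effect of the treatment on ECT2 and a failed estimate unrelated to length both stay open. In control, ECT2 occupancy was 0.441 inside the ends and 0.647 in the body. Genes listed at 0 in both control libraries had 1.12 ± 0.470 and 1.025 ± 0.498 (SD across genes). The highest quintile had 0.829 ± 0.283 and 0.879 ± 0.222. With such spreads these values do not decide between the 2 explanations, and no further test was made.

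The lower plastid transcripts may reflect a lower yield of all organelle RNA in the COR libraries, since mitochondrial transcripts were lower too, with a median log2 fold change of -0.258 over 13 transcripts. Zeros among plastid genes do not account for it: plastid transcripts above 0 in every library had a median of -0.417. An effect of coronatine on plastid transcription or RNA stability stays open as well, since no value here tells it from yield.

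The median change in occupancy inside gene ends was higher at genes whose mRNA rose than at other genes. Matching on mRNA level, on control occupancy and on gene length left the list at percentiles 99.98, 99.95 and 99.99, which argues against each of these as the whole cause. Genes lower with COR lay at percentile 91.54, inside the range of random lists, which would fit a change that goes with induction. Outside the ends, however, these lower genes lay at percentile 99.79, and in the body above all random lists. A raised change there was therefore not limited to induced genes, though in isolated genes their outside excess was 0.0062. Across tested genes, Spearman's rho between the change in mRNA and the change inside was -0.0034. The percentile of 91.54 shows no difference between the 2 lists inside the ends, so a direct comparison was added once it had been seen. The medians of the 2 lists differed by 0.0196, or 1.18 times their combined SD, and they cannot be told apart on that measure. Among genes with no neighbour within 500 bp their excess over other genes was 0.042 and -0.011, a wider gap for which no random lists were drawn, so whether the change goes with induction stays open. A difference between the pooled libraries that the treatment did not make also stays open, since there is 1 occupancy column per condition (1.0).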
